A study of Mus musculus with 9 samples.

How the data were processed

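Whole lumbar dorsal root ganglia (L3 to L5, on the side of the treated paws) of male C57BL/6 mice aged 8 to 10 weeks were profiled by stranded total RNA sequencing on an Illumina NextSeq instrument, with single-end reads of 75 nucleotides. The mice had received vehicle, cisplatin or oxaliplatin, and each drug was given into the paw to a cumulative dose of 40 µg. There were 9 libraries, 3 per group, and each library was made from RNA pooled from the ganglia of 4 animals. Variation between single animals was therefore not measured, and each pool counts as 1 replicate. The labels give no batch, date, cage or pairing between the groups.

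The deposited files hold counts, that is, raw reads per gene symbol for each library, with no normalization by the authors. The authors' processing notes name STAR, SAMtools and HTSeq without versions, and the mouse build mm10 (GRCm38). The annotation, the strand setting of the counting and any filter are not given in the sources used here, so reads from antisense or overlapping genes cannot be told from those of the named gene. Counts of genes with near-identical copies, such as the alpha and beta globin pairs and the replication histones, are uncertain too, because reads that aligned to multiple places were assigned to no gene. Each file covers 38926 genes and also records 5 classes of reads assigned to no single gene, which made up 42.8 to 74.5% of recorded reads and were left out of the gene comparisons. Symbols were looked up in the GENCODE M21 annotation, and 98.6% matched; gene identifiers, positions and exon lengths were taken from there.

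Differential expression was tested with edgeR 4.0.16 (limma 3.58.1, R 4.3.3). All 9 libraries were fitted together with 1 term per group, TMM scaling, the filterByExpr filter (17348 genes tested) and the quasi-likelihood F test, and the 3 contrasts were cisplatin against vehicle, oxaliplatin against vehicle and cisplatin against oxaliplatin. Changes are log2 fold changes. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called, and each standard error (SE) was computed as the size of the log2 fold change over the square root of F. Levels are read counts scaled to equal TMM-scaled library totals (CPM), as mean ± SD over the 3 libraries of a group. Intervals of a fold change are at 95% confidence. The detection floor was set at 3 counts in a library. Intervals of shares of reads (exact Clopper-Pearson) and floors cover counting error only, since the reads carry no molecular identifiers.

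Before the data were examined, 43 gene lists (pathways, the neuron and glia types of the ganglion, and other cell types that dissected tissue could hold), the groups, the contrasts, the rule for naming genes and most alternatives were fixed. Lists with at least 5 tested members were compared with all other genes by camera (limma) at its preset correlation of 0.01, two-sided, with adjustment over the lists of each contrast. Camera with the correlation estimated from the data was run beside it, as was fry, which tests whether the genes of a list move on balance in 1 direction and does not compare them with other genes. List members were also counted with p-values adjusted over the list alone. The agreement of the drug responses, which share the vehicle libraries, was set against 100 simulated data sets in which no group differed and both drugs were compared with the same vehicle libraries; the overlap of their calls was taken from 100 further such sets, fitted as the data were. Library properties were compared with two-sided exact permutation tests, which with 3 libraries against 3 cannot give a p below 0.1.

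Named genes follow a rule with these parts. They are 14 genes of neuropathy and nociception chosen in advance; the 10 largest increases and decreases per contrast among called genes whose groups do not overlap, with a mean of at least 1 CPM and no predicted-gene symbol; and the 10 smallest p-values where fewer than 10 genes passed. To these come the 4 members of smallest p in each list called by camera or 2 in each other list, and the 10 genes called against vehicle for both drugs whose larger p was smallest. Any other gene is said to have been chosen after its values were seen.

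Alternatives were median-ratio (DESeq2) size factors, library totals alone, no count filter or at least 1 CPM in 3 libraries, limma-voom, robust empirical Bayes, DESeq2 1.42.0, a term for the replicate number, fits of 2 groups only, an adjusted p of 0.1, removal of mitochondrial, small and structural RNAs, and leaving out each library in turn. The removal of these RNAs went by symbol and did not cover Gm26924, the most abundant gene of vehicle library 2. Chosen after the data were seen were removal of each library's trend with GC content and exon length (mgcv 1.9.3), a test against a 1.5-fold change, and a fit of protein-coding genes alone. The procedure was tested on simulated counts with 200 changed genes: it recovered 68, 71 and 72% of 1.5-fold changes and 81, 85 and 87% of 2-fold changes in the 3 contrasts, and 7.45, 3.70 and 10.2% of calls were false. In a simulated shift of the potassium channel list, that list was called and 0 other lists were. Genes were drawn independently in these simulations, so they do not test the preset correlation of camera where list members are correlated, as in the data. Figures were drawn with Python 3.11.15.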

Results

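Lumbar dorsal root ganglia hold the cell bodies of the sensory neurons that innervate the hind paw, together with satellite glia, Schwann cells, vessels and resident immune cells. Transcript levels were measured in 9 pooled libraries: 3 from vehicle-treated mice, 3 from cisplatin-treated mice and 3 from oxaliplatin-treated mice. Reads assigned to genes numbered 27803684, 22819185 and 32022672 in vehicle libraries 1 to 3. They numbered 31971613, 38168902 and 36292104 in the cisplatin libraries, and 38808509, 38261691 and 35520144 in the oxaliplatin libraries. The floor of 3 counts corresponded to 0.0711 to 0.188 CPM.

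The vehicle libraries differed from the drug libraries in what their reads held. Reads assigned to no annotated feature, called reads outside genes here, made up 33.6% ± 12.3 of uniquely aligned reads in vehicle (SD, n = 3), 18.8% ± 0.25 in cisplatin and 17.4% ± 0.664 in oxaliplatin. They may include intronic or antisense reads of annotated genes, since the counting settings are not given. No library of 1 group overlapped those of another in this share. The exact permutation p was 0.1 for each pair of groups, the smallest that 3 against 3 libraries allow (Benjamini-Hochberg 0.188 over 15 comparisons of library properties). Vehicle library 2 stood apart: 51.0% of its recorded reads aligned to multiple places, against 25.9 to 33.8% in the other libraries, and 47.7% of its unique reads lay outside genes (95% Clopper-Pearson interval 47.7 to 47.7%). Mitochondrial rRNA took 8.62% of its gene reads and its 10 most abundant genes 32.9%; its TMM factor was 0.700, against 0.960 to 1.10 elsewhere. Mitochondrial rRNA held 4.22% ± 0.462 of gene reads in cisplatin and 2.48% ± 0.345 in oxaliplatin (exact permutation p = 0.1). The first principal component of log2 CPM, with 51.9% of the variance, placed the vehicle libraries at -41.5 to -29.7 and all drug libraries between 8.85 and 26.6.

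**Figure D1:**
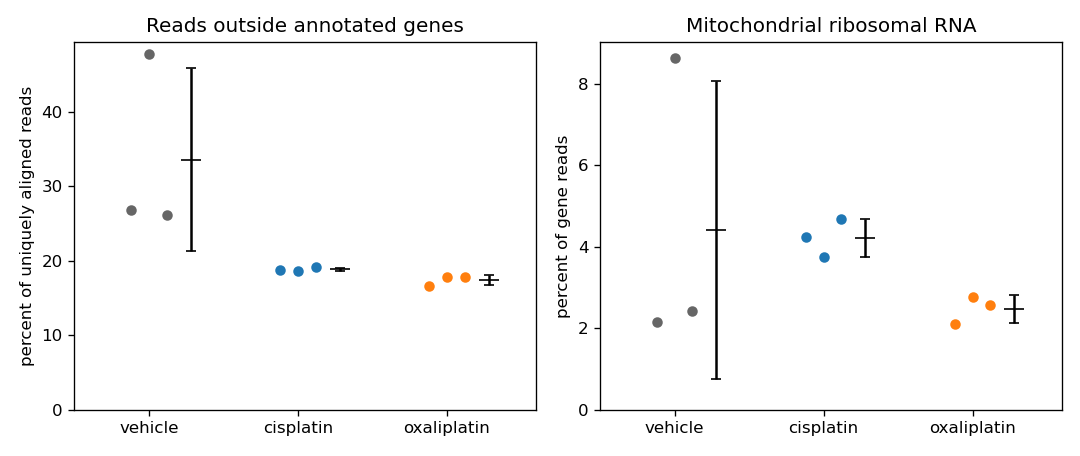
Left, reads assigned to no annotated feature (reads outside annotated genes) as a percent of uniquely aligned reads, by group. Right, mitochondrial rRNA as a percent of gene reads, by group. Points are libraries and bars are mean ± SD (n = 3). The vehicle libraries lie above all drug libraries on the left, and vehicle library 2 is the highest in both panels.

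Cisplatin was compared with vehicle to describe the ganglion's transcript signature after a drug that causes sensory neuropathy. Transcripts of ion channels that set sensory neuron excitability were lower, and those of myeloid cells, vessels, connective tissue and myelin were higher, as lists called by camera at its preset correlation. With an estimated correlation 0 of the 24 calls held (lowest adjusted p 0.410). Scn10a, which encodes the nociceptor sodium channel Nav1.8, fell from 1291 ± 64.7 to 804 ± 81.1 CPM (log2 fold change -0.68, SE 0.10, interval -0.91 to -0.46, adjusted p = 0.000376, n = 3 per group). Trpm8, the cold and menthol receptor, fell from 60.0 ± 4.92 to 31.5 ± 3.66 CPM (-0.93, SE 0.11, adjusted p = 9.18e-05). Calca, which encodes the neuropeptide CGRP, rose from 1254 ± 36.4 to 1635 ± 73.9 CPM (0.38, SE 0.08, adjusted p = 0.00331). Ltf, which encodes the neutrophil granule protein lactoferrin, rose from 10.1 ± 3.19 to 33.9 ± 6.62 CPM (1.79, SE 0.26, adjusted p = 0.000305). The 3 cisplatin libraries lay on 1 side of the 3 vehicle libraries for each of these genes, as for every gene named below as changed.

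In the edgeR fit, 6715 of 17348 genes changed, 2744 higher and 3971 lower, and 306 rose and 361 fell at least 2-fold. The groups did not overlap in 8322 genes, 48.0% of those tested, where chance gives 10%. The fit reports change relative to TMM scaling, which sets the median gene near 0. With library totals alone the median of all genes moved to 0.29 (0.16 without vehicle library 2), and 5987 of the called genes were higher and 917 lower. Part of that shift thus came from vehicle library 2, whose 10 most abundant genes held 32.9% of its gene reads. The values of single genes and lists under library totals below include that library and were not recomputed without it. The half-width of the 95% interval was 0.196 for the median gene, so changes smaller than that were mostly not detectable.

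Several channel groups fell, among genes that set how sensory neurons fire. Of 13 sodium channel genes tested, 10 fell, 1 rose and 2 did not pass (10 and 1 when adjusted over the list alone); the list median was -0.62 (camera adjusted p = 0.000376, and 0.417 with an estimated correlation). Scn9a, the Nav1.7 channel of nociceptors, fell from 1056 ± 80.3 to 668 ± 42.1 CPM. Scn7a, also a member of the non-myelinating and repair Schwann cell list, changed by -0.73. Under library totals the falls of Scn10a (-0.40, adjusted p = 0.0703) and Scn9a (-0.37, adjusted p = 0.0852) no longer passed, while the list median stayed below 0 at -0.33. Once each library's trend with GC content and exon length was removed, the list median was -0.26 (adjusted p = 0.00372). Of 33 potassium channel genes, 22 fell and 11 did not pass (26 fell when adjusted over the list alone), with a median of -0.40, or -0.12 under library totals (camera adjusted p = 1.83e-07, and 0.417 with an estimated correlation). Kcnq3, which carries the M-current, changed by -1.21, Kcnma1, the BK channel, by -1.05 and Kcnd1 by -0.84. Of 20 HCN and voltage-gated calcium channel genes, 18 fell (18 adjusted over the list alone), with a median of -0.58, or -0.29 under library totals (camera adjusted p = 1.02e-08, and 0.410 with an estimated correlation). Cacna1a, of the P/Q-type channel, fell from 128 ± 10.0 to 54.6 ± 7.31 CPM, and Cacna1b, of the N-type channel, changed by -1.08. Reads outside genes were higher in the vehicle libraries, as given above, and across all 17103 genes with an annotated length, which are not independent replicates, the fold change had a Spearman correlation of -0.413 with exon length.

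Markers of several neuron subtypes fell. Of 21 large-diameter neuron markers, 13 fell and 8 did not pass (14 fell over the list alone, median -0.42, or -0.13 under library totals; camera adjusted p = 8.13e-06, and 0.410 with an estimated correlation). Ntrk3, the receptor of proprioceptors and touch neurons, changed by -1.17 (SE 0.11) and Etv1, a proprioceptor transcription factor, by -0.91. Non-peptidergic and pruriceptor markers fell in 12 of 20 cases and rose in 1 (12 and 2 over the list alone), with a median of -0.27 that turned to 0.02 under library totals (camera adjusted p = 0.00205, and 0.410 with an estimated correlation). Mrgprb5, of the itch neuron receptor family, changed by -1.26, and Gfra2, a GDNF family receptor, by -0.62. C-LTMR and cold neuron markers fell in 7 of 11 cases (7 over the list alone), with a median of -0.24 that turned to 0.05 under library totals (camera adjusted p = 0.0274, and 0.410 with an estimated correlation); without cisplatin library 3 the list was no longer called (adjusted p = 0.0614). Its member Cdh8 changed by -0.41. Under library totals Gfra2 (-0.34, adjusted p = 0.0616) and Cdh8 (-0.12, adjusted p = 0.533) did not pass.

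Camera did not call the other neuronal lists. Fry called TRP, Piezo, ASIC and P2X channels (adjusted p = 0.00904) and pan-neuronal genes (0.0232) downward. Peptidergic nociceptor markers split, with 3 higher and 3 lower of 13 (3 and 3 over the list alone), a median of -0.05 (0.25 under library totals) against an upward test direction, and adjusted p = 0.929. In that list Tac1, which encodes substance P, rose from 209 to 247 CPM, a call lost without vehicle library 3 (adjusted p = 0.0659) or cisplatin library 1 (adjusted p = 0.0766). TRP, Piezo, ASIC and P2X channels had 1 member higher and 10 lower of 25 (the same over the list alone), with a median of -0.11 that turned to 0.18 under library totals (adjusted p = 0.0725); without cisplatin library 3 the list was called (adjusted p = 0.0384). Trpv1, the capsaicin receptor (-0.05, adjusted p = 0.619), and Trpa1, the irritant receptor (0.10, adjusted p = 0.270), did not pass. Pan-neuronal genes had 1 higher and 8 lower of 20 (median -0.16, 0.13 under library totals, adjusted p = 0.128), and were called downward without cisplatin library 3 (adjusted p = 0.0419) and after removal of the GC content and exon length trend (adjusted p = 0.0230). Their members did not move together: Map2, a dendritic microtubule protein, changed by -0.90, and Gap43, a growth cone protein, by 0.35. Nerve injury and regeneration genes had 6 higher and 7 lower of 31 (median 0.09, adjusted p = 0.597). Atf3, the transcription factor induced in injured neurons, was at 5.67 CPM in vehicle and 5.89 in cisplatin (0.05, adjusted p = 0.808); Gal (0.23, adjusted p = 0.272) and Csf1 (0.09, adjusted p = 0.391) did not pass, and Sema6a changed by -0.88. Npy had a mean of 0.0467 CPM in vehicle, below the floor, and 0.194 CPM in cisplatin (1.71, interval -0.43 to 3.85, adjusted p = 0.188); without cisplatin library 2 it passed (2.27, adjusted p = 0.0444). Under library totals, which moved all genes up, Gal (0.53, adjusted p = 0.00547), Csf1 (0.38, adjusted p = 0.0345), Trpa1 (0.39, adjusted p = 0.0298) and Npy (1.97, adjusted p = 0.0251) passed.

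Camera did not call the DNA damage response, repair or transporter lists, whose members went both ways. Fry called the repair list downward (adjusted p = 0.0205). Of 35 p53 targets 5 rose and 5 fell (4 and 5 over the list alone, median 0.03, mean -0.01, adjusted p = 0.715). Zmat3, a p53-induced RNA-binding protein, fell from 118 ± 15.1 to 59.0 ± 6.40 CPM, and Plk2 changed by 0.32. Cdkn1a, the cell cycle inhibitor p21, changed by -0.21 (adjusted p = 0.0548); it passed without vehicle library 3 (-0.26, adjusted p = 0.0368). Mdm2, the p53 ubiquitin ligase, fell from 40.0 to 34.3 CPM (-0.22, adjusted p = 0.00882), but was 0.07 under library totals and did not pass without vehicle library 1 (adjusted p = 0.0664). Of 30 repair genes 5 rose and 7 fell (median -0.03, 0.26 under library totals, adjusted p = 0.879). Rev3l, of translesion polymerase zeta, and Brca2 both changed by -0.68 (Brca2 -0.27, adjusted p = 0.0520 once the GC content and exon length trend was removed). Of 13 platinum and organic cation transporters, 1 rose and 4 fell (median -0.00, mean 0.03, 0.29 under library totals, downward test, adjusted p = 0.879), among them the copper ATPase Atp7a (-0.58; -0.29, adjusted p = 0.101 under library totals).

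Immune and blood lineage transcripts rose. Of 18 neutrophil and myeloid precursor markers 17 rose (17 over the list alone), with a median of 1.61 (camera adjusted p = 8.78e-10, and 0.410 with an estimated correlation). S100a8, a calcium-binding alarmin, rose from 15.0 to 55.8 CPM, Lcn2, the iron-trapping lipocalin, changed by 1.59 and Cxcr2, a neutrophil chemokine receptor, by 1.98. All 7 erythrocyte genes tested rose (7 over the list alone, median 1.90, camera adjusted p = 2.21e-05, and 0.410 with an estimated correlation). Hbb-bs, an adult beta globin, rose from 26.6 ± 2.65 to 97.8 ± 36.3 CPM, and Alas2, the erythroid haem synthesis enzyme, changed by 1.97. Of 25 macrophage markers 23 rose (23 over the list alone, median 0.67, camera adjusted p = 8.78e-10, and 0.410 with an estimated correlation), among them C1qb, from 8.94 ± 0.650 to 14.4 ± 1.15 CPM, and Tyrobp (1.11). MHC class II genes rose in 6 of 9 cases (9 over the list alone, median 0.41, camera adjusted p = 0.000713, and 0.417 with an estimated correlation), H2-DMb1 by 0.76 and Ctss by 0.65. Cytokines, chemokines and receptors rose in 7 of 29 cases (7 over the list alone, median 0.31, adjusted p = 0.00404, and 0.410 with an estimated correlation), including Ccl6 (1.20) and Il33 (0.60). Complement and acute phase genes rose in 9 of 15 cases (11 higher and 2 lower over the list alone, median 0.34, adjusted p = 0.00297, and 0.410 with an estimated correlation), with C3 at 0.80; that median was 0.21 without vehicle library 3 and 0.20 after trend removal. B and plasma cell markers had 6 higher and 1 lower of 12 (8 and 1 over the list alone, median 1.08, adjusted p = 0.0170, and 0.441 with an estimated correlation). At least 1 CPM in 3 libraries left that list uncalled (adjusted p = 0.227), and its member Cd79a (1.36) did not pass without vehicle library 1 (adjusted p = 0.0783). T and NK markers had 2 higher of 12, with a median of 0.54 (adjusted p = 0.0381, and 0.410 with an estimated correlation). Without 1 library, vehicle 1 (0.0751), vehicle 2 (0.0609), oxaliplatin 1 (0.0681) or cisplatin 3 (0.05003), the adjusted p of that list no longer passed. Interferon-stimulated genes had 0 higher and 3 lower of 29 (0 and 2 over the list alone) in edgeR, with a median of -0.09 that turned to 0.22 under library totals (adjusted p = 0.712). The list was called downward without vehicle library 1 (median -0.22, adjusted p = 0.0444), and without vehicle library 2 its median was 0.11, with 2 higher and 2 lower (adjusted p = 0.546). Its member Stat2 changed by -0.52 (-0.22, adjusted p = 0.224 under library totals). By unadjusted p 6 members were lower.

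Myelin, vessel and matrix genes rose as well. Of 24 myelinating Schwann cell genes 19 rose (20 higher and 1 lower over the list alone, median 0.37, camera adjusted p = 4.64e-07, and 0.417 with an estimated correlation). Prx, periaxin, and Pllp, plasmolipin, both changed by 0.60. Endothelial markers rose in 11 of 20 cases (14 over the list alone, median 0.45, adjusted p = 1.81e-05, and 0.417 with an estimated correlation), Plvap by 1.05 and Vwf by 0.75; without cisplatin library 1 the median was 0.29. Pericyte and smooth muscle markers rose in 6 of 14 cases (7 over the list alone, median 0.24, adjusted p = 0.0132, and 0.410 with an estimated correlation), with Myl9 at 0.90; without cisplatin library 1 the median was 0.11. Fibroblast and matrix genes rose in 21 of 28 cases (22 higher and 1 lower over the list alone, median 0.37, adjusted p = 9.63e-08, and 0.410 with an estimated correlation), with Fn1, fibronectin, at 0.70 and Col6a1 at 0.64. Leptomeningeal and nerve-sheath border markers, listed after the comparison was seen, were higher in the same libraries (17 of 22 higher, median 0.57, camera adjusted p = 4.62e-07 over 6 tests of such lists, and unadjusted p = 0.141 with an estimated correlation). Satellite glia markers had 3 higher and 5 lower of 21 (median -0.01, 0.27 under library totals, adjusted p = 0.597), with the adhesion gene Cadm2 at -0.94. Non-myelinating and repair Schwann genes had 2 higher and 5 lower of 12 (median -0.18, 0.10 under library totals, adjusted p = 0.389), with L1cam at -0.86. Markers of tissue outside the ganglion were mixed. Skeletal muscle markers had 0 of 17 changed in edgeR (1 by unadjusted p), with a median of 0.53 (adjusted p = 0.376), and Casq1 did not pass (0.84, adjusted p = 0.0811; 1.17, adjusted p = 0.00670 without cisplatin library 3). Adipocyte markers had 2 higher of 11 (1 over the list alone, median 0.31, adjusted p = 0.334), bone and cartilage markers 1 higher and 1 lower of 9 (0 and 0 over the list alone, median 0.16, mean -0.01, adjusted p = 0.591), and CNS glia markers 2 higher and 2 lower of 8 (median 0.21, adjusted p = 0.591), Gjb6 at 1.13 and Tnr at -0.90. Without cisplatin library 1 the skeletal muscle and CNS glia medians turned to -0.06 and -0.04, and without cisplatin library 3 the adipocyte median to -0.01.

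Housekeeping, proliferation and stress groups moved in both directions. Cytosolic ribosomal protein genes rose in 43 of 79 cases and fell in 1 (44 and 1 over the list alone, median 0.27, camera adjusted p = 6.14e-09, and 0.419 with an estimated correlation), with Rps28 at 0.49 and Rps4x at 0.43. Once the GC content and exon length trend was removed, the median was 0.09, with 19 higher and 2 lower (adjusted p = 0.00311). Nuclear oxidative phosphorylation subunits rose in 36 of 73 cases (40 over the list alone, median 0.18, adjusted p = 8.39e-09, and 0.419 with an estimated correlation), with Cox6a1 at 0.41 and Ndufv3 at 0.36. After the same removal that list's median was -0.01 and it was not called (adjusted p = 0.266). Of 13 mitochondrially encoded genes listed, 7 were tested and 3 were lower (median -0.58, or -0.27 under library totals, adjusted p = 0.253), with mt-Nd5 at -0.84. Without vehicle library 1 the list was called (median -0.72, adjusted p = 1.38e-05), and without vehicle library 2 its median was -0.14, with 1 higher and 3 lower (adjusted p = 0.574). Proliferation genes rose in 19 of 30 cases (20 over the list alone, median 0.56, adjusted p = 1.40e-06, and 0.410 with an estimated correlation), with Top2a at 0.97 and Mki67 at 0.73. The erythrocyte (median 1.90) and neutrophil and myeloid precursor markers (median 1.61), lineages with dividing precursors, were higher in the same libraries. Heat shock genes had 3 higher and 8 lower of 16 (3 and 9 over the list alone), with a median of -0.24 that turned to 0.05 under library totals (adjusted p = 0.0426, and 0.419 with an estimated correlation). The chaperone regulators Bag3 and Hsph1 changed by -0.88 and -0.84, and the small heat shock gene Cryab by 0.54. The heat shock call was lost without vehicle 1 (adjusted p = 0.0581), vehicle 2 (0.107), oxaliplatin 1 (0.0663), oxaliplatin 2 (0.0724) or cisplatin 2 (0.0574), with DESeq2 size factors (0.0522) and at 1 CPM in 3 libraries (0.0791); after trend removal it held, with a median of -0.12 (adjusted p = 0.0116). ER stress genes had 10 higher and 4 lower of 24 (12 and 4 over the list alone, median 0.14, adjusted p = 0.0375, and 0.410 with an estimated correlation), with Manf at 0.25 and Dnajb9 at -0.64 (-0.34, adjusted p = 0.0559 under library totals); the call was lost without vehicle library 2 (adjusted p = 0.0678). Oxidative stress genes had 9 higher and 2 lower of 20 (10 and 2 over the list alone, median 0.17, adjusted p = 0.0381, and 0.410 with an estimated correlation), with Prdx6 at 0.29 and Gclm at -0.40 (-0.10, adjusted p = 0.614 under library totals); without vehicle library 3 the list was not called (adjusted p = 0.0784). After trend removal the C-LTMR (0.0554), T and NK (0.0554), ER stress (median 0.01, 0.545) and oxidative stress lists (median 0.05, 0.386) did not pass. Not called were cholesterol synthesis (5 higher, 6 lower of 25; median -0.00, upward test, 0.30 under library totals, adjusted p = 0.879; Dhcr7 at -0.74) and immediate early genes (3 higher, 5 lower of 23; median 0.03, -0.11 without vehicle library 3, mean -0.10; adjusted p = 0.969). Clock genes (1 higher, 6 lower of 18, median -0.17, 0.11 under library totals, adjusted p = 0.334, Per1 at -1.06) and glucocorticoid-induced genes (2 higher, 3 lower of 15, median -0.07, 0.22 under library totals, adjusted p = 0.752, Zbtb16 at -0.80) were not called by camera either. Fry called the clock list downward (adjusted p = 0.0461).

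The 10 largest increases were Prg2, Itgb2l, Ifitm6, Hbb-bt, Trim10, Ly6c2, Hist1h3b, Cxcr2, Alas2 and S100a8, all at 1.97 to 3.15 and most known from granulocytes, monocytes or erythroid cells. Prg2, the eosinophil major basic protein, rose from 0.788 to 6.22 CPM (3.15, interval 1.84 to 4.46). The 10 largest decreases were Zfhx2, Pclo, Dgkk, Nr4a3, Clip3, Wasf1, AY036118, Wipf3, Raph1 and Meg3, at -2.07 to -1.73. Zfhx2, a homeobox transcription factor of nociceptors, fell from 32.2 ± 4.18 to 7.71 ± 0.632 CPM (SE 0.12), Pclo, a presynaptic scaffold, changed by -2.02 and the nuclear non-coding RNA Meg3 by -1.73. Camera called 24 of the 43 lists, 17 upward and 7 downward, and 0 held with an estimated correlation. Fry, which tests whether a list moves on balance in 1 direction and makes no comparison with other genes, called 29. Among them were the TRP, pan-neuronal, DNA repair, non-myelinating and repair Schwann, and clock lists, all downward, which camera did not call. In some called lists the number of members passing moved by over 1.5 times without 1 library. Without vehicle library 1 the higher members numbered 3 for MHC class II, 1 for B and plasma cell and 11 for proliferation genes. Without cisplatin library 1 they numbered 28 for ribosomal and 5 for ER stress genes, without vehicle library 3 they were 20 for oxidative phosphorylation, without cisplatin library 2 they were 5 for complement, and without vehicle library 2 they were 13 for cytokines.

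**Figure D2:**
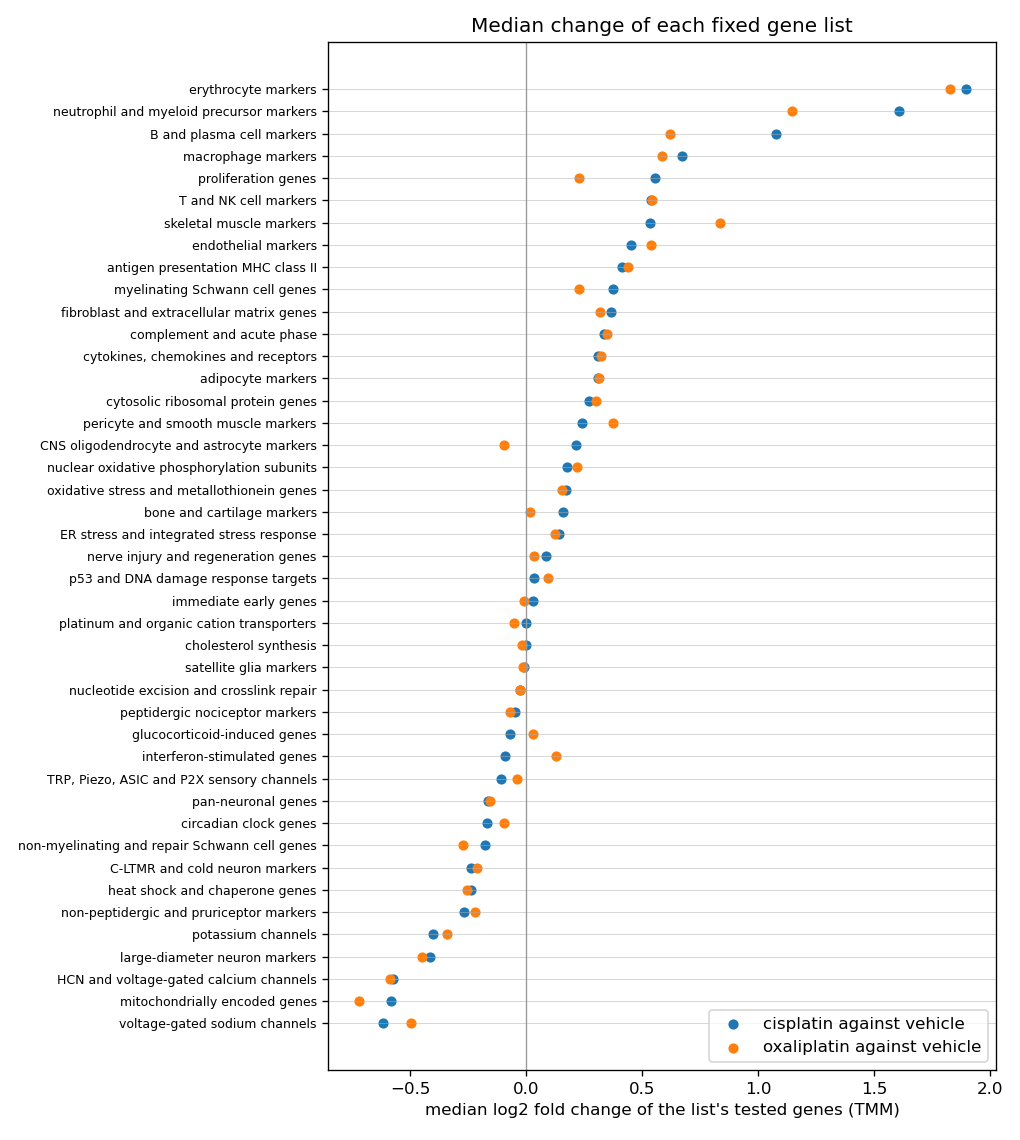
Median log2 fold change of the members of each of the 43 gene lists (x axis) for cisplatin (blue) and oxaliplatin (orange) against vehicle, scaled by TMM. Under library totals all medians shift up by about the all-gene median, so that TRP, non-peptidergic, C-LTMR, heat shock, pan-neuronal, non-myelinating Schwann, satellite glia, repair and clock medians lie above 0, while sodium, potassium, HCN and calcium channel, large-diameter neuron and mitochondrially encoded medians stay below 0.

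Oxaliplatin was compared with the same vehicle libraries to describe the signature of a drug that gives cold-evoked neuropathy in patients. The picture was close to that of cisplatin, with lower channel transcripts and higher blood lineage, vessel and matrix transcripts by camera at its preset correlation. With an estimated correlation 0 of the 19 calls held (lowest adjusted p 0.522), and the sodium channel call was also lost after trend removal (0.111). Trpm8 fell from 60.0 ± 4.92 to 33.4 ± 5.31 CPM (-0.84, SE 0.11, interval -1.08 to -0.60, adjusted p = 0.000127, n = 3 per group). Scn10a fell to 891 ± 109 CPM (-0.53, SE 0.10, adjusted p = 0.00162; -0.24, adjusted p = 0.288 under library totals). Calca rose to 1636 ± 111 CPM (0.38, SE 0.08, adjusted p = 0.00294), and Atf3, the injury-induced factor, from 5.67 to 8.22 CPM (0.53, SE 0.14, adjusted p = 0.00961), a call lost once the GC content and exon length trend was removed (0.32, adjusted p = 0.0961).

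In edgeR 7221 genes changed, 3043 higher and 4178 lower, with 246 rising and 419 falling at least 2-fold. Groups did not overlap in 8762 genes, 50.5% of those tested, where chance gives 10%. Under library totals 6408 genes were higher and 996 lower, with the all-gene median at 0.30 (0.17 without vehicle library 2). Single genes and lists under library totals were again not recomputed without that library.

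The channel groups fell here too. HCN and calcium channels fell in 17 of 20 cases and rose in 1 (18 and 1 over the list alone, median -0.59, or -0.29 under library totals, camera adjusted p = 6.12e-06, and 0.522 with an estimated correlation), with Cacna1a at 55.2 ± 9.64 CPM (-1.21). After removal of the GC content and exon length trend that median was -0.33 (adjusted p = 0.000519). Potassium channels fell in 22 of 33 cases (23 lower and 1 higher over the list alone, median -0.34, or -0.05 under library totals, adjusted p = 2.31e-05, and 0.522 with an estimated correlation), with Kcnq3 at -1.22. Sodium channels fell in 10 of 13 cases and rose in 1 (10 and 2 over the list alone, median -0.50, or -0.20 under library totals, adjusted p = 0.0201, and 0.630 with an estimated correlation). Scn9a changed by -0.60 and Scn7a by -0.63, and neither passed under library totals (-0.30, adjusted p = 0.166; -0.33, adjusted p = 0.133). The sodium channel call was lost without vehicle library 3 (adjusted p = 0.0817) and after trend removal (median -0.22, adjusted p = 0.111). Reads outside genes were again higher in vehicle, and the fold change had a Spearman correlation of -0.413 with exon length across genes. Large-diameter neuron markers fell in 12 of 21 cases (12 over the list alone, median -0.45, or -0.15 under library totals, adjusted p = 0.000155, and 0.522 with an estimated correlation), with the calcium sensor Vsnl1 at -1.56 and Ntrk3 at -1.01.

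Camera did not call the other neuronal lists for oxaliplatin. Fry called C-LTMR and cold neuron (adjusted p = 0.0114), non-peptidergic (0.0114), TRP, Piezo, ASIC and P2X channel (0.0302) and pan-neuronal lists (0.0223) downward. C-LTMR and cold neuron markers (6 lower of 11; median -0.21, 0.09 under library totals, adjusted p = 0.0501) passed without vehicle library 3 (0.0416), oxaliplatin 1 (0.0400) or oxaliplatin 3 (0.0419). Non-peptidergic markers (1 higher, 10 lower of 20; median -0.22, 0.08 under library totals, adjusted p = 0.0776; Mrgprb5 at -1.20) passed without oxaliplatin library 1 (0.0470) and after trend removal (0.00185). TRP, Piezo, ASIC and P2X channels had 2 higher and 9 lower of 25 (median -0.04, 0.26 under library totals, adjusted p = 0.418), with Trpv1 (-0.07, adjusted p = 0.463) and Trpa1 (0.06, adjusted p = 0.504; 0.36, adjusted p = 0.0428 under library totals) not passing. Pan-neuronal genes had 2 higher and 8 lower of 20 (median -0.16, 0.15 under library totals, adjusted p = 0.1246), with Map2 at -0.76, and passed after trend removal (adjusted p = 0.0278). Peptidergic markers had 2 higher and 3 lower of 13 (median -0.07, 0.23 under library totals, adjusted p = 0.726), and Tac1 (0.09, adjusted p = 0.352; 0.40, adjusted p = 0.0342 under library totals) and Gal (-0.05, adjusted p = 0.815) did not pass. Nerve injury genes had 9 higher and 6 lower of 31 (median 0.03, adjusted p = 0.522), with Sema6a at -0.92 and Csf1 not passing (0.18, adjusted p = 0.0711). Csf1 passed without vehicle library 2 (0.24, adjusted p = 0.0289) or cisplatin library 3 (0.21, adjusted p = 0.0316). Npy rose from 0.0467 to 0.336 CPM (2.56, interval 0.66 to 4.45, adjusted p = 0.0334), near the floor. That call was lost without vehicle 1 (adjusted p = 0.0773), vehicle 2 (0.0626), vehicle 3 (0.0882), oxaliplatin 1 (0.0866) or oxaliplatin 2 (0.0518).

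P53 targets again went both ways, with 7 higher and 9 lower of 35 (8 and 9 over the list alone, median 0.10, mean -0.01, adjusted p = 0.708). Cdkn1a fell from 26.5 to 18.7 CPM (-0.49, adjusted p = 0.000573; -0.18, adjusted p = 0.341 under library totals), and Zmat3 changed by -1.02. Mdm2 changed by -0.22 (adjusted p = 0.00810), was 0.08 under library totals and did not pass without vehicle library 1 (adjusted p = 0.0648). Repair genes had 7 higher and 5 lower of 30 (median -0.03, mean 0.00, 0.28 under library totals, upward test, adjusted p = 0.708), with Ercc1, of the excision nuclease, at 0.38 and Rev3l at -0.66. Transporters had 2 higher and 4 lower of 13 (median -0.05, 0.25 under library totals, adjusted p = 0.920).

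Blood lineage, vessel and matrix groups rose. Neutrophil and myeloid precursor markers rose in 13 of 18 cases (15 over the list alone, median 1.15, camera adjusted p = 0.000105, and 0.522 with an estimated correlation), with Ltf at 24.1 ± 7.91 CPM (1.30). Erythrocyte genes rose in 6 of 7 cases (6 over the list alone, median 1.83, adjusted p = 0.000467, and 0.522 with an estimated correlation), with Hbb-bs at 101 ± 41.7 CPM (1.93). Macrophage markers rose in 19 of 25 cases (21 over the list alone, median 0.59, adjusted p = 3.14e-07, and 0.522 with an estimated correlation), with C1qb at 15.1 ± 0.354 CPM (0.76) and Cx3cr1, the fractalkine receptor, at 0.87. MHC class II genes rose in 6 of 9 cases (6 over the list alone, median 0.44, adjusted p = 0.00714, and 0.529 with an estimated correlation), with H2-Eb1 at 0.48 (0.27, adjusted p = 0.0779 after trend removal). Cytokines and receptors rose in 8 of 29 cases (6 over the list alone, median 0.32, adjusted p = 0.0183, and 0.522 with an estimated correlation); the list call was lost without vehicle 1 (0.0534) or vehicle 3 (median 0.21, 0.0524), and after trend removal the median was 0.19 (adjusted p = 0.0432). Its member Ccr1 (1.26) did not pass without vehicle library 3 (adjusted p = 0.0562). Complement genes had 7 higher and 1 lower of 15 (the same over the list alone, median 0.35, adjusted p = 0.0277, and 0.522 with an estimated correlation), with C1s at 0.41, and that call was lost without vehicle library 3 (median 0.15, adjusted p = 0.0882) and after trend removal (median 0.12, adjusted p = 0.126); without oxaliplatin library 3 the median was 0.21. Endothelial markers rose in 14 of 20 cases (15 over the list alone, median 0.54, adjusted p = 6.12e-06, and 0.522 with an estimated correlation), with Plvap at 1.15. Pericyte markers rose in 7 of 14 cases (7 over the list alone, median 0.37, adjusted p = 0.00884, and 0.522 with an estimated correlation), with the KATP subunit Kcnj8 at 1.15. Fibroblast and matrix genes had 19 higher and 1 lower of 28 (21 and 1 over the list alone, median 0.32, adjusted p = 3.14e-07, and 0.522 with an estimated correlation), with Fn1 at 0.80 and Col6a1 at 0.72. The border markers were higher here too (16 of 22 higher, median 0.66, adjusted p = 9.44e-07, and unadjusted p = 0.157 with an estimated correlation). Myelinating Schwann cell genes had 11 higher and 1 lower of 24 (13 and 2 over the list alone, median 0.23, adjusted p = 0.00793, and 0.703 with an estimated correlation), with Pllp at 0.48 and Hmgcs1 at -0.31 (-0.01, adjusted p = 0.981 under library totals). Proliferation genes rose in 6 of 30 cases (2 over the list alone, median 0.23, adjusted p = 0.0167, and 0.522 with an estimated correlation), with Top2a at 0.60, in the libraries with higher erythrocyte and neutrophil precursor markers. Without vehicle library 1 fewer members were higher in several lists: 7 neutrophil, 11 macrophage, 8 endothelial and 5 myelinating Schwann cell genes. Ribosomal genes had 29 higher without oxaliplatin library 2. Cytokine calls numbered 2 without vehicle library 3 and 13 without vehicle library 2, and proliferation calls 2 without oxaliplatin library 3.

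Ribosomal protein genes rose in 44 of 79 cases and fell in 2 (47 and 2 over the list alone, median 0.30, adjusted p = 5.72e-09, and 0.522 with an estimated correlation). After trend removal the median was 0.12, with 23 higher and 4 lower (adjusted p = 0.00185). Oxidative phosphorylation subunits rose in 47 of 73 cases (49 over the list alone, median 0.22, adjusted p = 5.12e-10, and 0.522 with an estimated correlation), with Cox5b at 0.37; after trend removal the median was 0.02 (adjusted p = 0.0296). Mitochondrially encoded genes fell in 4 of 7 cases tested, of 13 listed (5 over the list alone, median -0.72, or -0.40 under library totals, adjusted p = 0.0282, and 0.596 with an estimated correlation), with mt-Nd5 at -1.18. That call was lost without vehicle 2 (median -0.38, 0.0667), vehicle 3 (0.0791) or oxaliplatin 1 (0.0644). Heat shock genes had 4 higher and 8 lower of 16 (the same over the list alone), with a median of -0.26 that turned to 0.05 under library totals (adjusted p = 0.0117, and 0.522 with an estimated correlation), and Hspa1b and Bag3 at -1.07 and -0.96; after trend removal the median was -0.14 (adjusted p = 0.00256). Not called were the oxidative stress (8 higher, 3 lower of 20; adjusted p = 0.0670), ER stress (9 and 3 of 24; 0.145; Dnajb9 at -0.86), T and NK (2 and 0 of 12; 0.0748), B and plasma cell (1 and 1 of 12; 0.140), skeletal muscle (0 and 0 of 17 in edgeR, 4 and 1 by unadjusted p; median 0.84; 0.223), adipocyte (1 and 1 of 11; 0.342) and bone lists (0 and 0 of 9 in edgeR and by unadjusted p; 0.681). Also not called were the interferon-stimulated (1 and 1 of 29; median 0.13, -0.02 without vehicle library 1; 0.334), satellite glia (3 and 5 of 21; 0.708; Kcnj10 at -0.96 and Cadm2 at -1.14), repair Schwann (1 and 6 of 12; 0.356) and CNS glia lists (1 and 3 of 8; median -0.09, mean 0.11, 0.19 under library totals; 0.968; Gjb6 at 1.34). Cholesterol synthesis (6 and 6 of 25; median -0.02, 0.29 under library totals, upward test; 0.968; Dhcr7 at -0.80), immediate early (3 and 7 of 23; median -0.01, 0.28 under library totals; 0.853), glucocorticoid-induced (0 and 3 of 15; median 0.03, mean -0.07; 0.968) and clock genes (5 and 6 of 18; median -0.10, mean 0.07, 0.20 under library totals, upward test; 0.853; Npas2 at -0.82 and Tef at 0.44) did not pass either. Without 1 library some of these passed: oxidative stress without vehicle 2 (0.0298), oxaliplatin 1 (0.0443) or cisplatin 1 (0.0380), interferon-stimulated genes upward without vehicle 2 (0.0294), and skeletal muscle without oxaliplatin 3 (0.00300). Camera called 19 lists, 13 upward and 6 downward, and 0 held with an estimated correlation. The lists given as not called in this paragraph are those that camera did not call. Fry, which makes no comparison with other genes, called 25 lists. Among them were oxidative stress (adjusted p = 0.0338), ER stress (0.0173) and T and NK markers (0.0133), upward, and repair Schwann genes (0.0254), downward. Fry did not call the neutrophil and myeloid precursor list (adjusted p = 0.0611) or the myelinating Schwann cell list (0.140), which camera had called upward.

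The largest increases were Prg2 (2.54, to 4.06 CPM), Slc22a6, Hbb-bs, Fgfbp1, Itgb2l, Hba-a1, Alas2, Hbb-bt, Hba-a2 and Ranbp3l. Slc22a6, an organic anion transporter, changed by 2.11 (SE 0.37), Fgfbp1, an FGF carrier, by 1.87 and Ranbp3l by 1.80. The largest decreases were Lars2, mt-Rnr1, Meg3, Zfhx2, Clip3, Nr4a3, Lmtk3, Scrt2, Wasf1 and Snhg11. Meg3 changed by -2.17, Zfhx2 by -2.16 (to 7.22 ± 1.17 CPM) and the neuronal kinase Lmtk3 by -2.02. Lars2 (-8.11) and mt-Rnr1 (-3.08) rested on vehicle library 2: without it they were -0.37 (adjusted p = 0.673) and -0.57 (adjusted p = 0.191), and without oxaliplatin library 3 the mt-Rnr1 call was lost as well (adjusted p = 0.0516).

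The changes of both drugs were compared gene by gene. Across all tested genes, which are not independent replicates, the log2 fold changes of the drugs against vehicle had Pearson r = 0.909 and Spearman rho = 0.899. In 100 simulations without any group difference and with genes drawn independently, sharing the vehicle libraries gave r = 0.573 (0.538 to 0.610). The covariance there was 0.0223 against the observed 0.210. Shifts common to many genes of a library were not simulated, so the shared vehicle libraries may account for more than these values. The sign was the same in 89.1% of genes, against 68.4% in the simulations. Against vehicle, 2183 genes were higher and 3551 lower for both drugs, where independent lists of these sizes would share 481 and 956. Separate handling of the vehicle libraries cannot be told apart from treatment in these counts. In 100 simulations without any group difference at most 1 gene in each direction was called for both drugs. At an unadjusted p under 0.05, both drugs shared 105 higher and 90.9 lower genes on average in those simulations, against 10.1 in each direction for independent lists and 2999 and 4114 observed. The value for independent lists leaves out the shared vehicle libraries, which are too few to split, so part of the excess over it may come from them. There was 1 gene called in opposite directions. Genes called for both drugs with the smallest larger p included Snhg11, a neuronal non-coding RNA (441 ± 14.3 CPM in vehicle, 136 ± 4.18 in cisplatin and 117 ± 5.72 in oxaliplatin), and Zfhx2. Others were Luc7l2, a splicing factor (-0.92 and -1.11), Fmn2, an actin nucleator (-1.05 and -1.23), and Rfx7, a transcription factor (-1.31 and -1.41).

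**Figure D3:**
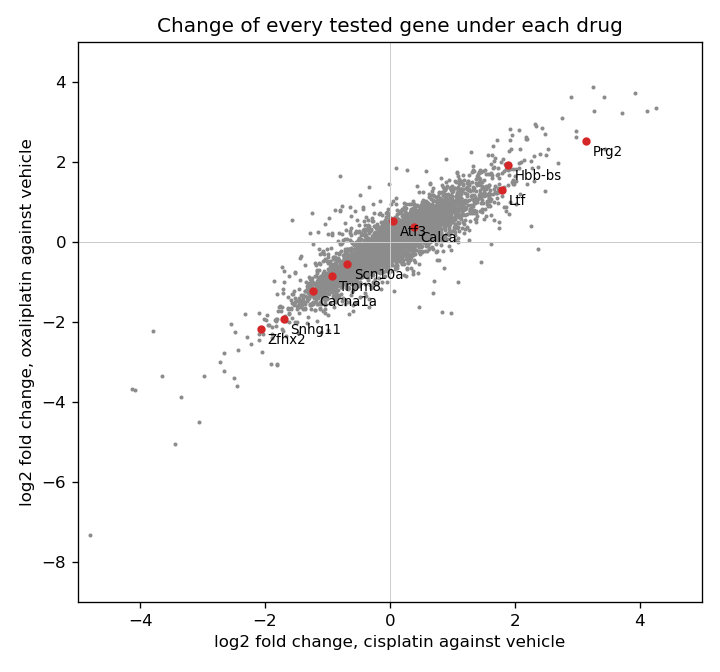
Log2 fold change against vehicle for cisplatin (x axis) and oxaliplatin (y axis), 1 point per tested gene, with some named genes in red; 3 genes lie outside the axes. The points follow the diagonal, with Prg2, Hbb-bs and Ltf at the upper right and Cacna1a, Snhg11 and Zfhx2 at the lower left.

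Cisplatin and oxaliplatin are both platinum complexes, cisplatin with ammine and chloride ligands and oxaliplatin with a diaminocyclohexane and an oxalate ligand, and were given to the same cumulative dose of 40 µg. Direct comparison found 2 genes, both higher after cisplatin. Fam150b, which encodes a ligand of the receptor tyrosine kinases ALK and LTK, was at 13.7 ± 0.725 CPM after cisplatin, 9.13 ± 0.380 after oxaliplatin and 8.61 ± 0.189 in vehicle (0.58, interval 0.43 to 0.73, adjusted p = 0.0468, n = 3). Prss34, a mast cell and basophil protease, was at 1.02 ± 0.218, 0.172 ± 0.0359 and 0.217 CPM (2.54, interval 1.82 to 3.26, adjusted p = 0.0495).

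By unadjusted p 1111 genes were under 0.05, and the groups did not overlap in 2453 genes (14.1%, where chance gives 10%). Both calls were lost without any 1 library other than vehicle 2, with adjusted p from 0.0636 without vehicle library 1 to 0.420 for Fam150b and 0.468 for Prss34 without oxaliplatin library 3. Leaving out any 1 library other than vehicle 2 or oxaliplatin 1 gave 0 genes in edgeR, while DESeq2 on all libraries called 16 genes and limma-voom 1. Without oxaliplatin library 1, 2 genes were called, both lower after cisplatin; they were Dbp (-1.75, adjusted p = 0.000966) and Per3 (-0.97, adjusted p = 0.0359).

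For most genes the drugs could not be told apart with these libraries, and the intervals bound how far they differed. For the median gene the 95% interval reached 0.189 to each side. The difference, cisplatin minus oxaliplatin, was -0.24 (interval -0.48 to 0.00) for Scn11a, the Nav1.9 channel, and -0.16 (-0.46 to 0.13) for Cacna1b. Atf3 was called against vehicle after oxaliplatin alone, and its difference was -0.48 (-0.77 to -0.19, adjusted p = 0.596). For Cdkn1a the difference was 0.28 (0.11 to 0.45, adjusted p = 0.599). Bdnf, a neurotrophin of nociceptors, was 0.39 higher after cisplatin (0.26 to 0.52, adjusted p = 0.151), and did not pass. Other genes with small p-values did not pass in edgeR either, among them Sh3bgrl (0.40, adjusted p = 0.223), Hnrnph1 (0.25, 0.241), Arxes2 (0.34, 0.285), and the clock output and repressor genes Dbp, Nr1d2 and Per3. Dbp was at 20.2 ± 8.49 CPM after oxaliplatin, 7.22 ± 0.997 after cisplatin and 7.28 ± 0.103 in vehicle (-1.48, interval -2.01 to -0.95, adjusted p = 0.198). Nr1d2 was -0.45 (adjusted p = 0.284), Per3 -0.81 (adjusted p = 0.285) and Nr1d1, another REV-ERB repressor, -1.33 (adjusted p = 0.5004).

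Between the drugs, camera called 14 lists although 0 list members passed over all genes in edgeR (67 higher and 35 lower of 901 by unadjusted p), and 0 lists held with an estimated correlation. Fry, which does not compare a list with other genes, called 0 lists (lowest adjusted p 0.0902). After cisplatin the neutrophil list was higher (median 0.49, adjusted p = 4.66e-11, and 0.656 with an estimated correlation), with Mpo at 0.70 and Csf3r at 0.35, neither passing. Proliferation genes were higher (0.29, adjusted p = 3.45e-11, and 0.178 with an estimated correlation; 8 higher and 1 lower over the list alone), with Mki67 at 0.67 and Kif11 at 0.29, as were myelinating Schwann cell genes (0.15, adjusted p = 3.01e-09, and 0.671 with an estimated correlation; 1 higher over the list alone), with Fa2h, a myelin lipid enzyme, at 0.42. Mitochondrially encoded genes (0.27, adjusted p = 0.00197, and 0.731 with an estimated correlation; mt-Nd1 at 0.27) were higher too, with mitochondrial rRNA also higher in the cisplatin libraries, and were not called after trend removal (0.14, adjusted p = 0.2005). B and plasma cell (0.24, adjusted p = 0.0175, and 0.731 with an estimated correlation; Cd79a at 0.78) and macrophage markers (0.10, adjusted p = 0.0458, and 0.912 with an estimated correlation; Itgam at 0.40) were also higher; at 1 CPM in 3 libraries the B and plasma cell list was not called (0.05, adjusted p = 0.517). Without 1 library these medians moved: neutrophil to 0.27 (without oxaliplatin 1), myelinating Schwann to 0.08 (without cisplatin 1) and 0.24 (without cisplatin 3), macrophage to 0.04 and 0.17 (the same libraries). The B and plasma cell median was 0.10 without oxaliplatin 1 and 0.58 without oxaliplatin 3.

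After oxaliplatin, interferon-stimulated genes were higher (median, cisplatin minus oxaliplatin, -0.19, adjusted p = 4.38e-07, and 0.731 with an estimated correlation), with Mx1 at -0.83 and Ifit3 at -0.54, neither passing. Clock genes were higher as well (-0.17, adjusted p = 5.76e-05, and 0.554 with an estimated correlation; 4 lower and 7 higher after oxaliplatin over the list alone). Smaller medians were found for sodium channels (-0.09, adjusted p = 0.00707, and 0.732 with an estimated correlation), HCN and calcium channels (-0.09, 0.0196, and 0.884), and non-peptidergic markers (-0.07, 0.00121, and 0.573). The same held for TRP channels (-0.05, 0.0175, and 0.671), repair genes (-0.04, 0.0411, and 0.554; Xpa, the damage verification factor, at -0.35, the 1 lower member over the list alone; 0.133 after trend removal, so that the call was lost) and oxidative phosphorylation subunits (-0.04, 0.0175, and 0.912; Ndufa7 at -0.12). Of the 14 calls 6 were kept without oxaliplatin library 1, 8 without cisplatin library 1 and 11 without cisplatin library 2; repair genes were also lost without oxaliplatin library 3 (0.127), oxidative phosphorylation without oxaliplatin library 2 (0.984) or cisplatin library 3 (0.150). Without oxaliplatin library 1 the medians of interferon-stimulated genes (-0.11), sodium channels (-0.05) and HCN and calcium channels (-0.01) were nearer 0, as was that of non-peptidergic markers (-0.05), and those of clock genes (-0.29) and oxidative phosphorylation (-0.07) farther. Without oxaliplatin library 2 the median was -0.14 for HCN and calcium channels, -0.11 for non-peptidergic markers, -0.06 for repair genes and -0.01 for oxidative phosphorylation. Without oxaliplatin library 3 the clock median was -0.08, without cisplatin library 3 the TRP median was -0.08 and the HCN and calcium channel median -0.13, and without cisplatin library 1 the latter was -0.05. After trend removal 12 of the 14 calls were kept. Leaving out 1 library gave 9 calls (without oxaliplatin library 1) to 21 (without cisplatin library 3). The other 29 lists were not called with all libraries; among them satellite glia held Fabp7 at 0.37 (adjusted p = 0.342). Without 1 library some of these passed. Without cisplatin library 3 they were potassium channels (lower after cisplatin, 0.000280), large-diameter markers (lower, 0.00930), erythrocyte (higher, 0.000548), MHC class II (higher, 0.00815), cytokine (higher, 0.00815), fibroblast (higher, 0.0141) and CNS glia lists (higher, 0.0172). Without cisplatin library 1 endothelial (lower, 3.92e-06) and pericyte markers (lower, 0.0344) passed, and without cisplatin library 2 peptidergic markers (higher, 0.0349). Skeletal muscle (lower, 4.45e-09) and complement (higher, 0.0133) passed without oxaliplatin library 3, and ribosomal protein (lower, 0.000828) and heat shock genes (higher, 0.0189) without oxaliplatin library 1. The library with the lowest adjusted p is given for each list, and some passed without others as well.

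**Figure D4:**
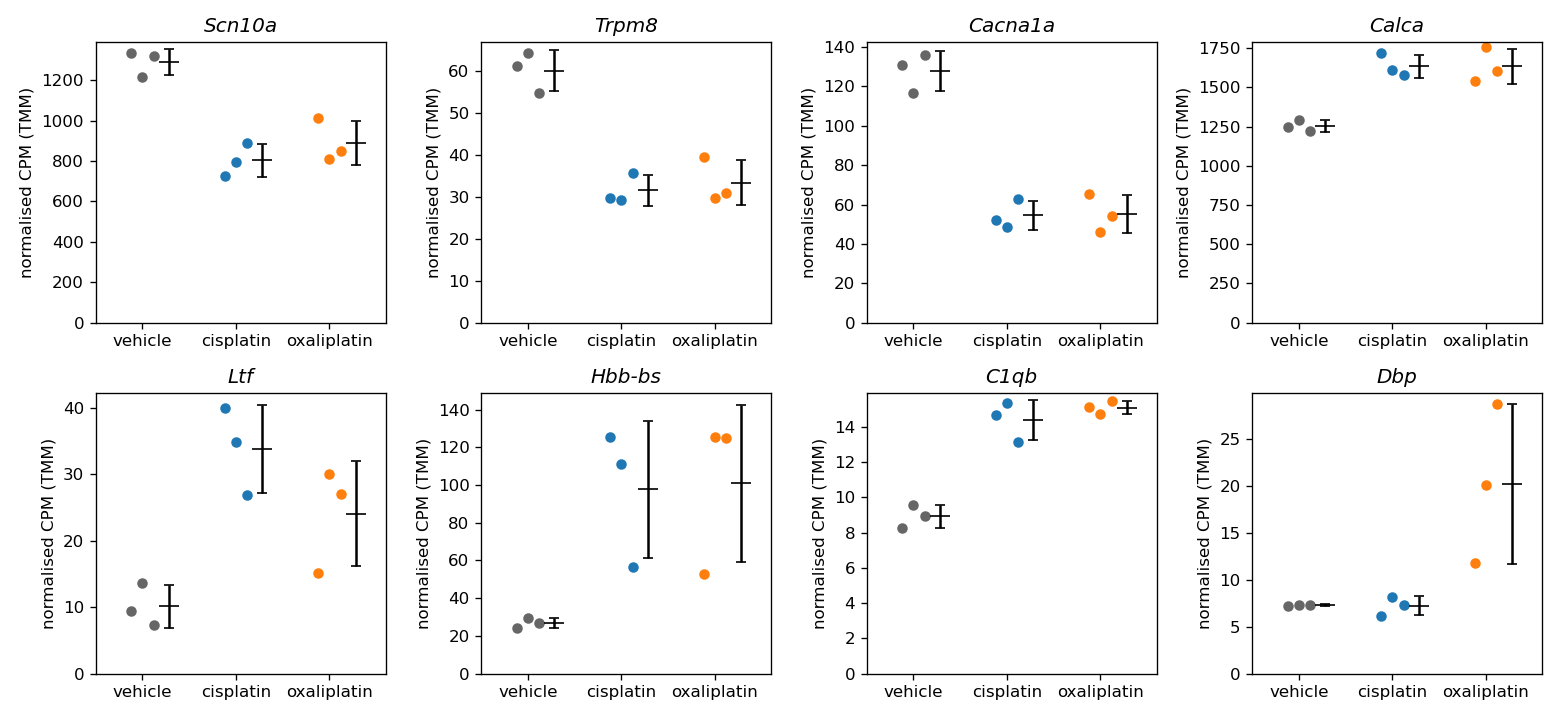
CPM on TMM-scaled totals of 8 genes (y axis, 1 panel per gene) in vehicle, oxaliplatin and cisplatin libraries; points are libraries and bars are mean ± SD (n = 3). Scn10a, Trpm8 and Cacna1a lie lower and Calca, Ltf, Hbb-bs and C1qb higher in both drug groups than in vehicle, and Dbp is highest in oxaliplatin; under library totals the Scn10a falls do not pass.

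On GRCm38, Scn10a (ENSMUSG00000034533) lies on chromosome 9 at 119608456 to 119719322, Trpm8 on chromosome 1 at 88277661 to 88389293, and Calca on chromosome 7 at 114631478 to 114636357. Hbb-bs lies on chromosome 7 at 103826534 to 103828096, and Ltf on chromosome 9 at 111019271 to 111042767. Zfhx2 lies on chromosome 14 at 55060262 to 55092324, Fam150b on chromosome 12 at 30884322 to 30893854, and Prss34 on chromosome 17 at 25298394 to 25300165.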

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

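The tests of the GC content and exon length trend, of separate handling of the vehicle libraries, of the ratio of blood lineages and of progenitor genes were chosen only after the result was seen; the others were written before their values were known, though part of the clock genes had raised the pattern they test.

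Fam150b was singled out because the drugs differed directly, with a log2 difference of 0.58 (cisplatin minus oxaliplatin). Prss34, the other gene past the threshold in that comparison, differed by 2.54. Of the 10 splits of these 6 libraries, 3, counting the real one, called at least 2 genes (2 genes real, 4 the highest of the others), and 10 splits are too few for a share under 0.05.

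List medians past the camera threshold between the drugs were higher after cisplatin for neutrophil markers (0.49), proliferation (0.29), mitochondrially encoded genes (0.27), B and plasma cell markers (0.24), myelinating Schwann cell genes (0.15) and macrophage markers (0.10). They were higher after oxaliplatin, given as cisplatin minus oxaliplatin, for interferon-stimulated genes (-0.19), clock genes (-0.17), sodium channels (-0.0892), HCN and calcium channels (-0.0854), non-peptidergic markers (-0.0739), TRP channels (-0.0462), repair genes (-0.0394) and oxidative phosphorylation (-0.0352). Of the 10 splits, 6, counting the real one, called at least 14 lists (14 real, 22 the highest of the others), again too few splits for a share under 0.05. The median correlation estimated within lists was 0.169, against camera's preset 0.01, and with estimated correlations 0 lists were called.

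Reads overlapping more than 1 gene, which no comparison of genes used, made up 0.490% of unique reads on average in the 6 drug libraries and 0.345% ± 0.105 in vehicle (exact permutation p = 0.1 for each drug against vehicle, the smallest 3 against 3 libraries allow; Benjamini-Hochberg 0.188).

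Many genes differed between vehicle and each drug, and trends with GC content and exon length are argued against as the whole cause, since 60.8% of oxaliplatin calls and 63.1% of cisplatin calls kept sign and threshold after their removal. More nuclear and incompletely spliced RNA in the vehicle libraries is a candidate explanation for part of it. The 15 tested detained-intron and nuclear-retained transcripts had medians of -0.29 for cisplatin and -0.38 for oxaliplatin. These lay at the 0.93 and 0.1 percentiles of 10000 random lists matched for size and mean expression (camera p = 0.0174 and 0.00500 with an estimated correlation). Exon length and GC content were not matched, and the list was not tested after trend removal. The percentiles and p-values therefore cannot separate nuclear RNA from those trends. The vehicle libraries also held more reads outside genes, but the list differed between the drugs as well, by 0.12 at percentile 100 (camera p = 0.0111 with an estimated correlation). A block of transcription elongation by platinum, as a biological explanation, would lower long genes: the slope on log10 gene span was -0.15 for each drug, with every drug library below every vehicle library. Of it 23.5% (cisplatin) and 16.9% (oxaliplatin) was left at fixed exon length, where the cisplatin libraries (-0.0190 to -0.0134) still lay below the lowest vehicle library (-0.00302) and the oxaliplatin libraries (-0.0136 to 0.00910) overlapped vehicle, so it stays open. Separate handling of the vehicle libraries stays open and cannot be told apart from treatment, since all vehicle libraries are on 1 side; the highest correlation across genes of a drug library's deviation from its group with that axis (0.398 for oxaliplatin, 0.295 for cisplatin) decides nothing, because such deviations sum to 0 within a group.

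Genes changed against vehicle were also counted in the 10 splits of each pair of groups. Only the real one (1 split) called as many genes (6715 and 7221, against 0 in the highest other). The other splits mix vehicle and drug libraries, so a group difference widens their spread, and the 0 calls there say little about chance. Counting the real one, 3 splits for cisplatin and 5 for oxaliplatin called as many lists (24 and 19 real, 26 and 22 the highest of the others). Such sets of 10 splits are too few for a share under 0.05.

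Clock genes differed between the cisplatin and oxaliplatin libraries, and a different time of day at collection, which would move Arntl and Npas2 against Dbp, the Per genes and Nr1d1, may account for it: the phase measure made of these, named before the data were examined, differed by 1.35. Dbp, Per3 and Nr1d1 had raised the pattern, so their part (-1.21) tests nothing. Of the others, Arntl and Npas2 were on average 0.56 higher after cisplatin, with no overlap of libraries (exact permutation p = 0.1, the smallest 3 against 3 libraries allow), and Per1 and Per2 were at -0.17, with overlap (exact permutation p = 0.5). GC content and exon length trends are argued against, as the difference was 1.34 after their removal. The time of collection is not given in the sources used here, so a drug effect on the clock stays open and was not tested.

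Transcripts of blood lineages were higher in the drug libraries. Whether mature blood leukocytes alone account for this stays open. The progenitor genes Mpo, Elane, Prtn3 and Ctsg had a median of 1.61 for cisplatin, beside 1.89 for mature neutrophil genes (0.80 and 1.42 for oxaliplatin). Fold changes do not show which cells the transcripts came from, so these medians do not decide it. Marrow or blood of 1 fixed composition, carried over at dissection in different amounts, stays open: the log2 ratio of neutrophil to erythrocyte transcripts was 0.46 higher after cisplatin, but the closest libraries of the drug groups were 0.171 apart, too close for the ratio to decide. Neutrophil list transcripts were at 52.5 to 121 CPM in vehicle, 107 to 235 in oxaliplatin and 199 to 311 in cisplatin, and erythrocyte list transcripts at 40.4 to 57.6, 86.4 to 211 and 101 to 218. Entry of such cells into the ganglion after treatment is an untested alternative that these values do not separate from carry-over.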

How the results depend on the processing

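The removal of the GC content and exon length trend, the 1.5-fold threshold and the protein-coding fit were chosen after the data were seen. Against vehicle the counts of changed genes stayed within 1.5 times of 6715 and 7221 in every alternative run except the 1.5-fold threshold, which gave 390 (58 higher, 332 lower) and 433 (33 higher, 400 lower) by its construction. The removal of mitochondrial, small and structural RNAs (6712 and 7217) left in Gm26924, which held 14.8% of the gene reads of vehicle library 2. Those counts therefore do not test the influence of that gene. They ranged over left-out libraries from 4881 (without vehicle 1) to 7309 (without vehicle 2) for cisplatin, and from 5342 (without oxaliplatin 2) to 7697 (without vehicle 2) for oxaliplatin; 91.5 and 91.7% of the calls remained without vehicle library 2. Between the drugs the count of 2 became 68 with library totals (30 higher, 38 lower), 16 without a count filter, 16 in DESeq2, 1 at 1 CPM in 3 libraries, 1 in limma-voom, and 0 with a replicate block, with the 2 groups alone and at the 1.5-fold threshold, and was 0 to 2 over left-out libraries; the cause was not tested. The replicate numbers did not pair the libraries: deviations of same-numbered libraries correlated at -0.14 to 0.11 across genes. With the replicate block the heat shock list for cisplatin (adjusted p = 0.0617) and the mitochondrially encoded list for oxaliplatin (0.0653) were no longer called, and the heat shock list was called between the drugs (0.0300). With an estimated correlation camera called 0 lists for cisplatin, 0 for oxaliplatin and 0 between the drugs; between the drugs left-out libraries gave 9 to 21 lists. The adjusted p of oxidative phosphorylation between the drugs ranged from 4.19e-07 (without oxaliplatin 1) to 0.984 (without oxaliplatin 2), and that of fibroblast genes from 0.0141 (without cisplatin 3) to 0.946 (without oxaliplatin 3). Without oxaliplatin 2 the test direction of the former turned while its median stayed below 0 (-0.01), and without cisplatin 3 the median of the latter turned from -0.02 to 0.04; the cause was not tested. Mdm2 reversed to 0.0670 (cisplatin) and 0.0780 (oxaliplatin) under library totals, which raise all genes. Of 3289 values of named genes under alternatives, 3192 kept the side of the threshold, 60 lost the call, 35 gained it and 2 reversed direction. Direction was not compared where neither the reported value nor the alternative passed. The correlation of the drugs' changes was 0.874 to 0.916 over left-out libraries. Pools of 4 animals, 3 libraries per group and floors of 0.0711 to 0.188 CPM limit what could be detected.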

Other observations

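The test of border cell markers was written before its values were known, but after the genes that prompted it had been seen.

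Slc22a6, Fgfbp1 and Ranbp3l, among the largest increases after oxaliplatin, are known from the coverings of nerve and brain. A list of leptomeningeal and nerve-sheath border cell markers that left out these 3 genes had a median of 0.66 for oxaliplatin, with 16 of 22 members higher, and 0.57 for cisplatin, with 17 higher. Camera passed it for both drugs (adjusted p = 9.44e-07 and 4.62e-07), but with an estimated correlation the p was 0.157 and 0.141. Between the drugs its median was -0.01. More sheath tissue in the drug libraries is a candidate explanation, and growth of that tissue after treatment was not tested. Fibroblast genes, which such tissue also expresses, rose in the same libraries.

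Lars2 was far higher in vehicle library 2 than in the other vehicle libraries, at 37512 CPM against 57.7 and 60.7 CPM; it is 1 of the named decreases after oxaliplatin that rest on that library.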
